A study of Arabidopsis thaliana with 2 samples.

How the data were processed

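Total RNA of 10-day seedlings was extracted with Trizol, polyadenylated RNA was selected on oligo(dT) beads, and fragmented cDNA was sequenced on an Illumina HiSeq, per the labels' protocols. There were 2 libraries, 1 of wild type and 1 of the crwn1 crwn2 double mutant, grouped by the genotype label. No statement of strand was found in the sources used here, so reads from overlapping genes on opposite strands cannot be told apart.

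The deposited counts are whole numbers of uniquely placed reads per transcript model, per the file headers, and their sum equals the total in each header, 2094440 in wild type and 2203650 in crwn1 crwn2. The authors' RPKM values equal those counts divided by model length and by the header total. The deposited coverage column gives the percent of each model's length covered by reads. The genome build was TAIR10, per the submitters' processing notes. The aligner, the counting rule and the read filters are not given in the sources used here. Models with 1 read had 49 bp covered. The files list 21768 models in wild type and 22373 in crwn1 crwn2, and a model with no read is not listed. Models of loci with several transcript models had a median coverage of 5.25% and 5.13%, against 56.6% and 60.6% for loci with 1 model, so reads shared by models of the same locus appear to be uncounted, and the levels of such loci are too low in both libraries. CRWN2, KAKU4, NTL9, ICS1, AT1G13609, SEN1, ASN1 and MYB28, named below, are loci with several models. Loci whose only listed model was their first held 97.6% and 97.7% of reads. Such a locus can have further models that are not listed, so it may still lose shared reads. In wild type, reads covered only 6.91% of WRKY18, 6.99% of XTH9 and 10.3% of RAB18, which counted as loci with 1 model. Gene families with near-identical copies, such as antenna proteins, histones, extensins and lipid-transfer proteins, can also lose or exchange reads and are uncertain.

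Reads and RPKM were summed per locus. The main value was the log2 ratio of RPKM + 1, mutant over wild type. A gene was measured if it reached an RPKM of 1 and 10 reads in at least 1 library, which 14393 of 21808 loci did. It was called if it differed at least 2-fold and the exact conditional binomial (Clopper-Pearson) 95% interval of the ratio of reads excluded equality. PCR copies are not independent molecules, so these intervals cover counting error only. A gene with 0 reads in 1 library was set against a floor of 3 counts, equal to a CPM of 1.43 in wild type and 1.36 in crwn1 crwn2. Ratios against that floor are not bounds, so the limit of the exact 95% interval nearer to equality is given for such genes. No test between genotypes and no p-value was computed.

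Gene lists, the calling rule and the alternatives were fixed before the data were examined. There were 27 lists with 494 genes, after 3 entries were left out because the TAIR10.1 reference table gives their identifiers other names (DLO1, RPW8.1 and RPW8.2). Each list's median was placed among 10000 random lists of the same size, drawn with replacement from 20 bins of mean expression, as a description of these 2 libraries. Its counting range came from 1000 Poisson redraws of the reads. Of 21808 loci, 21651 matched the reference table, which was used for names and gene types. Coordinates are those of the files. Genes within 2.5 Mb of approximate centromere positions were compared with the rest, and calls were shuffled 1000 times over measured genes for the count of adjacent pairs.

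Genes were named by a rule. CRWN1 to CRWN4, KAKU4, NTL9, PR1, PR2, PR5 and ICS1 were always named. The 12 called genes with the largest and the 12 with the smallest log2 ratio were named among nuclear genes with an RPKM of at least 5 in the higher library. Up to 4 members with the largest absolute ratio were named from each list outside the 2.5th to 97.5th percentile, and 1 from each other list. Other genes, such as LOX2, AT5G35935, SPCH, PUB23, CML37, PYK10, AT4G22485 and AT4G22505, were chosen after their values were seen. For further observations, 4 lists of 64 genes were written after the main results and before their own values were read, and 15 families were formed from product names after the values were seen. When a named gene was compared between alternatives, its counting interval was extended where needed to hold the main value.

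Alternatives were a pseudocount of 0.1, an RPKM floor of 5, no floor, TMM scaling with edgeR 4.0.16 (factors 0.954 in wild type and 1.05 in crwn1 crwn2), CPM, thresholds of 4-fold and 1.5-fold, a width of 1.5 Mb and random lists without matching. A set restricted to loci with 1 listed transcript model was added after seeing the data. It may still hold loci with further, unlisted models. In simulated counts with 200 altered genes for crwn1 crwn2 against wild type, over 14180 genes, 62 of 66 genes altered 3-fold, 67 of 67 altered 4-fold and 66 of 66 altered 8-fold were called, as were 138 of 13981 unaltered genes. The simulation held Poisson counting error only, so these rates leave out variation between plants, harvests and libraries. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3 were used.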

Results

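Polyadenylated RNA from 10-day Arabidopsis thaliana seedlings was sequenced in 1 wild-type library and 1 library of the crwn1 crwn2 double mutant. CRWN1 and CRWN2 encode long coiled-coil proteins of the plant nuclear lamina, the meshwork that lines the inside of the nuclear envelope, and the comparison asked which transcripts differed in seedlings lacking both. The wild-type library held 2094440 uniquely placed reads on 20223 loci and the mutant library 2203650 reads on 20701 loci. A locus had a median of 24 reads in wild type and 26 in the mutant. With 1 library per genotype the differences have no replicate check, no test between genotypes was run, and the intervals of read ratios cover counting error only. Intervals of the late jasmonate and root hair comparisons are bootstraps over genes. They treat genes of the same 2 libraries as independent and do not measure variation between plants. Harvest and library preparation cannot be separated from genotype. Ratios are of the mutant over wild type, on a log2 scale after adding 1 to the RPKM, which understates the difference of weakly expressed genes.

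CRWN1 and CRWN2 transcripts were both far lower in the library labelled as the double mutant. CRWN1 (AT1G67230, chromosome 1, 25151270 to 25156323 on the TAIR10 build) had 1021 reads in wild type and 57 in the mutant, 18.8-fold fewer for equal library totals (exact 95% interval 14.4 to 25.1), and reads covered 94.2% of the transcript in wild type against 25.3% in the mutant. CRWN2 (AT1G13220, chromosome 1, 4515606 to 4520284) had 148 and 9 reads, 17.3-fold fewer (8.87 to 38.6). It is a locus with several transcript models, and its RPKM values of 19.6 and 1.77 gave a smaller difference, a log2 ratio of -2.90. CRWN3, the paralog left intact, had 351 and 434 reads, with a log2 ratio of 0.23, and KAKU4, which encodes a lamina partner of the CRWN proteins, had 17 and 19 reads. KAKU4 is a locus with several transcript models, and reads covered 4.37% and 3.94% of the model listed. CRWN4 was listed in neither library, which is no measure of its expression because reads shared between transcript models of a locus appear to be uncounted. NTL9, a NAC transcription factor gene, had 19 reads in wild type and 8 in the mutant, a log2 ratio of -0.99, not called, and called lower after TMM scaling (-1.08). Among 13 measured genes of the nuclear envelope and pore, none passed the 2-fold rule. Their median log2 ratio was 0.18, and WIP2, an outer envelope protein gene, had the largest difference at -0.83.

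Of 14393 measured genes, 912 were at least 2-fold higher in the mutant library and 652 at least 2-fold lower, with a counting interval that excluded equality. The remaining genes included most of the transcriptome, since 88.2% of measured genes lay within 2-fold. The median log2 ratio of all measured genes was 0.12, and TMM scaling shifted the ratio of read totals by -0.14, less for weakly expressed genes because of the added 1, which turned the split to 686 higher and 819 lower. Some list medians below are therefore also given relative to the median of all measured genes. At the top of the range stood AT3G01345 (chromosome 3, 129138 to 130749), annotated as an expressed protein, with 3 reads in wild type and 273 in the mutant, a ratio of 86.5 (29.3 to 422). Next came AT1G47395 and AT1G47400, which encode IRONMAN peptides of iron-deficiency signalling, with 0 reads in wild type and 22 and 16 in the mutant, at least 6.97-fold and at least 5.07-fold higher. The defensin-like gene AT1G13609 had 0 and 11 reads, at least 3.48-fold higher. AT2G30766, a further IRONMAN gene, had 1 and 22 reads (ratio 20.9, 3.38 to 863). The small heat shock gene AT1G59860 had 4 and 69 reads. ATSDI1, a sulphur-deficiency gene, had 1 and 37 reads, the proline-rich protein gene ATPRP1 had 1 and 41, the arabinogalactan protein gene ATAGP30 had 3 and 60, and AT5G54370, annotated as a late embryogenesis abundant protein, had 2 and 51. At the other end, AT4G33720, a gene of the family that holds PR1, had 44 reads in wild type and 0 in the mutant, at least 15.4-fold lower. AT3G29970 and the VQ-motif gene AT1G21326 were at least 3.86-fold and at least 4.56-fold lower. The VQ-motif gene AT2G22880 had 108 and 8 reads, and PHI-1, a phosphate-responsive cell wall protein gene, had 918 and 88. The ERF-family gene AT1G77640 had 214 and 22 reads, AT3G55840, annotated as Hs1pro-1, had 182 and 16, and the xyloglucan endotransglucosylase gene XTR3 had 57 and 4. AT3G43850 had 26 reads against 1 and the non-coding locus AT2G01422 had 24 against 1.

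**Figure D1:**
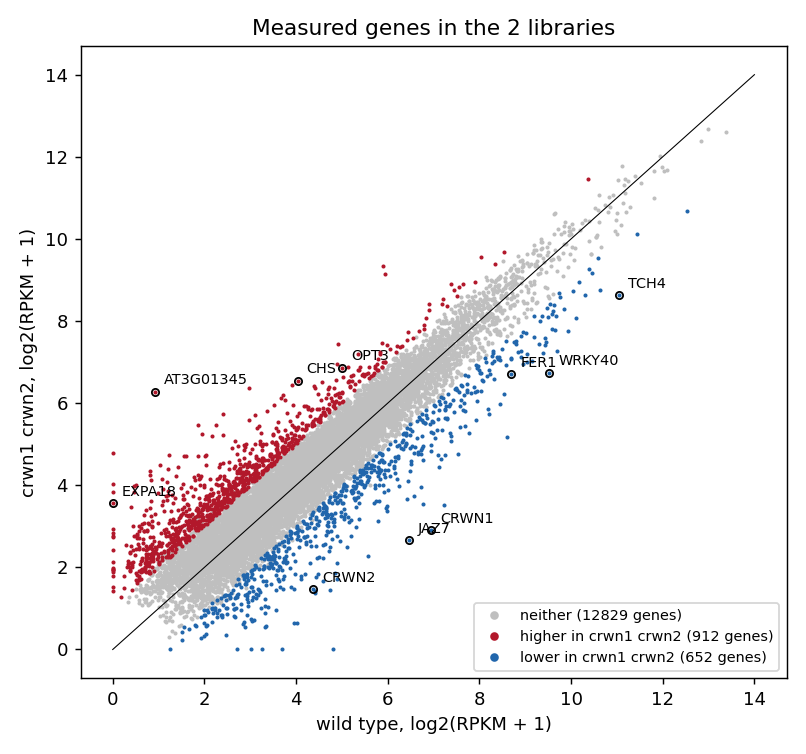
Each point is 1 of 14393 measured genes, with log2(RPKM + 1) in the wild-type library on the x axis and in the crwn1 crwn2 library on the y axis. Genes called higher (912) are red, genes called lower (652) are blue, circles mark named genes, and CRWN1 and CRWN2 lie far under the line of equal values.

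Most jasmonate genes were lower in the mutant library. Of 22 measured genes of jasmonate synthesis and response, 12 were lower and 1 was higher. Their median log2 ratio was -1.18, or -1.302 relative to all measured genes, under all 10000 random lists matched on expression. The repressor genes JAZ7 (123 and 8 reads) and JAZ8 (24 and 2 reads) had log2 ratios of -3.79 and -3.03. CYP94B3, a jasmonate-catabolic enzyme gene, and LOX3, a lipoxygenase of jasmonate synthesis, had ratios of -2.84 and -2.52, whereas the lipoxygenase gene LOX2 had a ratio of 1.52. All 8 measured genes of the jasmonate and ethylene defence list were below 0, 5 of them called lower, with a median of -1.42. ERF1 had 18 and 1 reads, and the ethylene response factor genes ERF6, ERF2 and ERF1A had log2 ratios of -2.15, -1.73 and -1.50. Of 12 genes of ethylene synthesis and signalling, only ACS6, an enzyme gene of ethylene synthesis, passed the rule (-1.28), and the median of -0.26 lay inside the range of the random lists. After TMM scaling 2 of the 12 were called lower. The clock genes, listed as a check of harvest time, had a median of -0.48, with 2 of 11 called lower. The list holds genes that peak at different times of day, so its median alone does not measure harvest time.

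Lists of immune signalling genes had medians below 0, while several pathogenesis-related genes were higher. Among 28 measured immune receptor and signalling genes, 7 were lower, none was higher and 21 were not called, with a median log2 ratio of -0.53 (-0.65 relative to all measured genes), under all 10000 matched lists. After TMM scaling 9 of these genes were lower. The transcription factor genes WRKY40 (1834 and 280 reads) and WRKY33 (2762 and 715 reads) had ratios of -2.77 and -2.02, the chitin receptor gene LYK5 -1.86 and the kinase gene MPK3 -1.58. Genes that respond within minutes to touch or wounding, a sign of handling, were lower in the same library (17 of 24, median -1.48). In the list of salicylic acid synthesis and signalling, 5 of 20 genes were lower and 2 were higher, with a median of -0.52. After TMM scaling 8 were lower and 2 higher. The glutaredoxin gene GRXC9 (-3.18), the salicylic acid receptor gene NPR3 (-1.85) and WRKY18 (-1.59) were lower and WRKY54 (1.40) was higher. Reads covered only 6.91% and 5.3% of WRKY18. ICS1, which encodes the main salicylic acid synthesis enzyme, had 1 and 2 reads, too few for a comparison. Reads shared by its transcript models may be uncounted. In contrast, 6 of 11 pathogenesis-related and salicylic-acid-responsive genes were higher and 1 was lower, with a median of 1.07, or 0.49 with no expression floor. PR1 had 10 and 47 reads, 4.47-fold more for equal library totals (2.23 to 9.92), PR5 had 2 and 16 (7.60-fold, 1.79 to 68.2), and EARLI1, a lipid-transfer-like gene, had 64 and 186. PR2, a glucanase gene, had 14 and 10 reads, a difference inside its counting interval, and PCC1, a circadian and pathogen-responsive gene, had 23 and 2 reads.

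Genes of abscisic acid and cold, sugar starvation, the clock, senescence and auxin formed 5 further lists with medians under the 2.5th percentile of matched lists. For 15 abscisic acid and cold genes the median was -0.48 (-0.25 with no expression floor), with 4 lower and 1 higher; the cold regulator genes CBF1 and CBF2 had log2 ratios of -1.62 and -1.39 and KIN1 1.14, and the dehydrin gene RAB18, at -1.07, did not pass the counting interval. Sugar starvation genes had a median of -0.78, with 3 of 9 lower, among them ASN1 (17 and 3 reads), an asparagine synthetase gene, BT2 (-1.13) and TPS8 (-1.01), and TPS9 had a ratio of -0.85. Of 11 clock genes 10 were below 0 and 2 were called, PRR7 (-1.60) and GI (-1.01), while TOC1 and BOA had ratios of -0.85 and -0.84. The senescence list had a median of -0.30, with SEN1 (-2.05) and SAG29 (-1.83) lower and SAG21 (-0.93) and the metacaspase gene MC1 (-0.41) not called. After TMM scaling SAG21 was called lower (-1.07). In the auxin and growth list, with a median of -0.31, the touch-responsive wall enzyme gene TCH4 had 4694 and 932 reads (-2.40) and XTH15 307 and 49 (-2.66), while XTH9 (1.63) and the auxin-conjugating enzyme gene GH3.3 (1.04) were higher. GH3.3 was not called after TMM scaling (0.91). Reads covered only 6.99% and 7.92% of XTH9.

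Root markers were higher in the mutant library, led by genes of root hairs. Of 13 measured root markers, 8 were higher and none was lower, with a median log2 ratio of 1.59 (1.48 relative to all measured genes), over all 10000 matched lists. The root hair expansin genes EXPA18 and EXPA7 had 0 reads in wild type and 24 and 14 in the mutant, at least 7.60-fold and at least 4.44-fold higher. PRP3, a root hair wall protein gene, had 7 and 96 reads (13.0-fold, 6.09 to 33.3), and LRX1, an extensin-like gene, had 4 and 46. Iron genes gave a median of 1.06 over 9 measured members, with 5 higher and 1 lower. OPT3, an iron transporter gene of the phloem, had 159 and 623 reads (1.86), the nicotianamine synthase gene NAS4 9 and 39 (1.79), and the ferric reductase gene FRO2 0 and 10, at least 3.17-fold higher. FER1, which encodes the iron-storage protein ferritin, had 1234 and 326 reads (-1.98).

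Flavonoid and heat shock genes were higher as well. For the flavonoid and anthocyanin list, 7 of 8 measured genes were higher, with a median of 1.66 (1.55 relative to all measured genes). CHS, the entry enzyme gene of flavonoid synthesis, had 48 and 304 reads, 6.02-fold more for equal library totals (4.43 to 8.34). The regulator gene MYB111 had 2 and 21 reads, the transport gene TT19 1 and 11, and the reductase gene DFR 1 and 13. Heat shock genes had a median of 1.59 over 9 members, with 6 higher and 1 lower. HSP17.6A had 1 and 27 reads (25.7-fold, 4.23 to 1051), HSP17.4 had 4 and 29, HSP17.6II 1 and 10, and HSP15.7 3 and 12. HSP15.7 was not called after TMM scaling.

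Cell cycle genes were shifted upward as a group, with all 16 measured members above 0 and 9 called higher. The median log2 ratio was 1.05, or 0.94 relative to all measured genes, and over all 10000 matched lists. The replication factor gene PCNA1 had 15 and 60 reads (1.79), the mitotic cyclin gene CYCB1;1 11 and 44 (1.65), the cytokinesis gene KNOLLE 60 and 181 (1.48) and the cyclin gene CYCA1;1 20 and 57 (1.299). The DNA damage and endoreduplication list had a median of 0.53 (0.30 with no expression floor and 0.35 with an RPKM floor of 5), with 2 of 12 higher, TSO2 (1.68), a ribonucleotide reductase gene, and GMI1 (1.11, and 0.99 and not called after TMM scaling), and with PARP2 (0.95) and PARP1 (0.92) not called. All 8 measured DNA methylation and silencing genes were above 0, with a median of 0.66, or 0.32 with no expression floor. Only the demethylase gene ROS1 (1.05) was called, and it was not called after TMM scaling (0.92); the chromomethylase gene CMT3, the methyltransferase gene MET1 and the remodeller gene DDM1 had ratios of 0.85, 0.80 and 0.78. Camalexin and indolic defence genes had a median of 0.54, with the camalexin enzyme genes CYP71A12 (1.65) and CYP71A13 (1.12, not called after TMM scaling) higher, CYP83B1 at 0.82 and the regulator gene MYB51 lower (-1.68). Aliphatic glucosinolate genes had a median of 0.48, with only 1 of 14 called, the regulator gene MYB28 (1.14), a locus with several transcript models, and with UGT74C1, AOP2 and CYP79F2 at 0.99, 0.95 and 0.77.

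The remaining lists, apart from the CRWN family, lay inside the range of random lists. Photosynthesis genes had a median of -0.12 over 38 members and 4 lower, including LHCB1.1 (1020 and 347 reads), an antenna protein gene whose reads can be shared with near-identical copies. The oxidative stress list went both ways, with 4 of 11 higher, such as GSTU25 (2.25), 3 lower and a median of -0.26, which became 0.12 with an RPKM floor of 5. Phosphate starvation genes had a median of 0.34 (0.20 with no expression floor), yet the non-coding RNA gene AT4 had 508 and 95 reads (-2.47). Only 4 flowering genes were measured (median -0.38, or -0.17 with no expression floor, KNAT2 -0.95) and 1 seed gene, OLEO2, with 12 and 3 reads. The CRWN family list, which contains both mutated genes, had a median of -1.41, or -2.90 with an RPKM floor of 5. In all, 20 of 27 lists lay outside the central 95% of their random lists, 10 on either side. Random lists were drawn gene by gene. A list whose genes vary together can therefore lie outside them between any 2 samples, and its percentile does not measure a genotype effect.

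**Figure D2:**
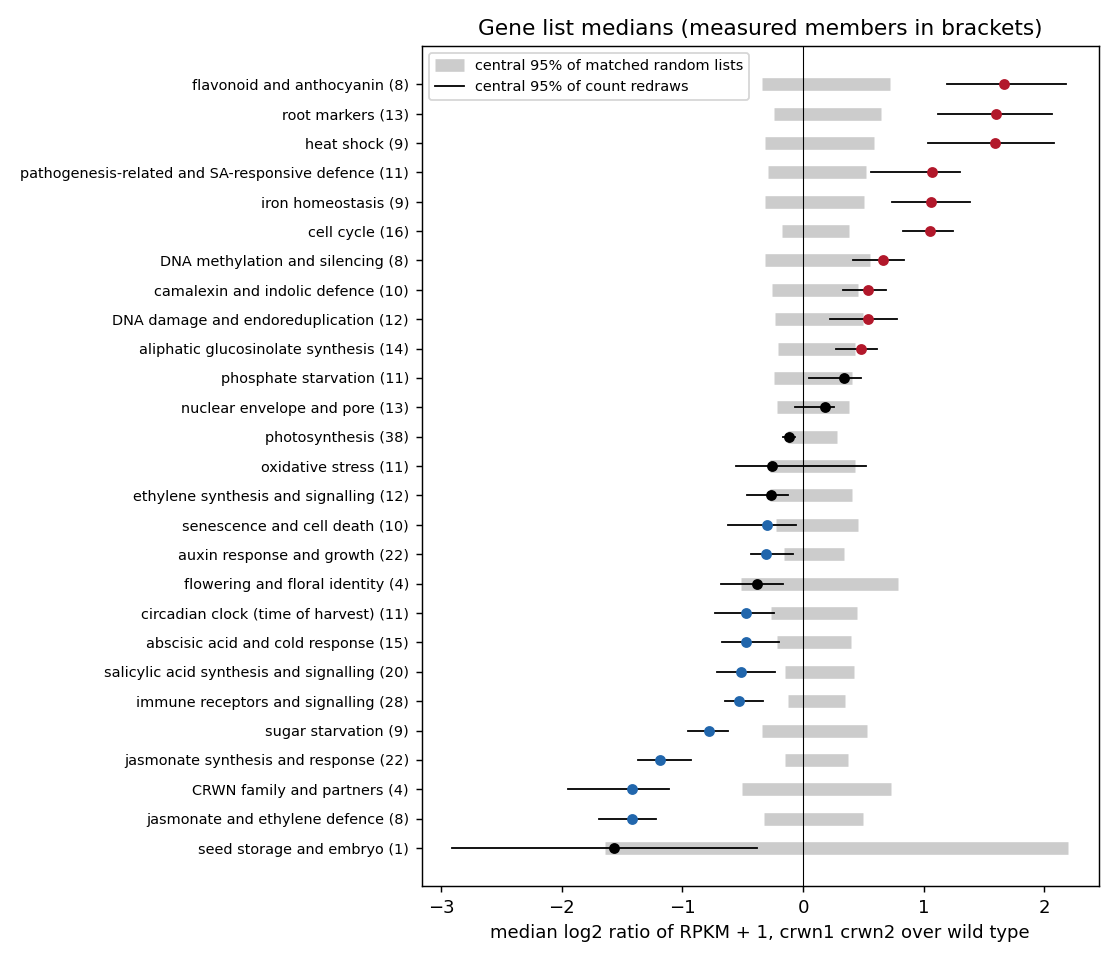
Median log2 ratio of RPKM + 1 (crwn1 crwn2 over wild type, x axis) for each of 27 gene lists, with the number of measured genes in brackets. Grey bars span the central 95% of 10000 matched random lists, black lines the central 95% of 1000 count redraws, and red and blue points mark the 20 lists outside the grey range.

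By uniquely placed reads, transposable element genes were not higher as a class. They took 0.334% of reads in wild type and 0.323% in the mutant, a ratio of 0.970 (exact 95% interval 0.938 to 1.002), and of 81 measured loci 3 were higher and 3 lower, with a median log2 ratio of 0.05 that became -0.0646 after TMM scaling. AT5G35935, chosen after its values were seen, had 5 and 100 reads. Plastid-encoded genes took 2.204% and 2.15% of reads. Mitochondria-encoded genes took 0.0946% and 0.116% although their median log2 ratio was -0.46, so the share and the median differ in sign. Nuclear non-coding loci had a median of -0.16, with 12 of 103 lower and 4 higher.

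Genes near the centromeres did not stand apart from those on chromosome arms. The median log2 ratio was 0.14 for 716 genes within 2.5 Mb of a centromere and 0.12 for 13598 others, at the 80.8th percentile of matched random sets. The difference of 0.02 became -0.0414 for genes within 1.5 Mb. Called genes made up 11.9% of the pericentromeric and 10.8% of the other genes. Neighbouring genes, by contrast, were called together more often than in shuffled data. Of 14309 adjacent pairs, 142 had both genes called in the same direction, against a mean of 86.7 and a maximum of 120 in 1000 shuffles. Without the 19 pairs of genes that share a product name, 123 remained, against a mean of 84.9 and a maximum of 117. Duplicates with different names and unstranded reads across overlapping genes were not removed from that count.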

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

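The restriction to loci with 1 listed transcript model was chosen after the data were seen, unlike the other alternatives. With 1 library per genotype, none of them replaces a replicate. No called gene among the named ones reversed its direction in 640 comparisons over 109 named genes. The floors leave a ratio unchanged, and TMM scaling shifted the ratio of read totals by only -0.14. A reversal of a 2-fold difference was therefore hardly possible, and its absence is no evidence of robustness. KAKU4, which was not called, had a log2 ratio of 0.07 and -0.04 under TMM scaling. Among the named genes, 4 moved out of their counting interval, all under TMM scaling. TMM scaling gave 686 genes higher and 819 lower, where the RPKM gave 912 and 652, and 1338 calls were shared. It moved the medians of immune receptors to -0.66, photosynthesis to -0.25, auxin response to -0.45, plastid-encoded loci to -0.30, transposable element loci to -0.0646 and nuclear protein-coding loci to -0.00518. A threshold of 4-fold gave 129 higher, 108 lower and 14 adjacent pairs, and 1.5-fold gave 1993, 1194 and 497. With no floor the medians became 0.49 for pathogenesis-related genes, -0.84 for jasmonate genes, -1.20 for jasmonate and ethylene defence, 0.32 for DNA methylation and -0.0611 for non-coding loci, with weakly expressed members included. An RPKM floor of 5 gave -2.90 for the CRWN family, -1.38 for jasmonate genes, 2.201 for flavonoid genes, 0.12 instead of -0.26 for oxidative stress and 0.11 for nuclear protein-coding loci, with fewer genes. A pseudocount of 0.1 gave 2.204 for flavonoid genes. Loci with 1 listed transcript model gave 0.13 for nuclear protein-coding loci. Pericentromeric genes within 1.5 Mb lay -0.0414 from the rest, and the cause was not tested. Without matching on expression, 3 lists passed outside their random lists, at percentiles of 1.81 for ethylene, 1.03 for photosynthesis and 1.69 for seed genes, and the 20 others stayed on their side. Depth limits genes under about 10 reads, including IRT1 and most seed and flowering genes. ICS1 has several transcript models, so its few reads may also reflect uncounted shared reads.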

Other observations

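Families defined by product name, SPCH, PUB23, CML37, PYK10 and the run of lipid-transfer-like genes were chosen after the values were seen, as were the tests over all root hair genes below; the other tests were set beforehand. Several families had medians over those of matched lists in the crwn1 crwn2 library. Of 11 measured extensin-like genes 10 were higher, with a median log2 ratio of 2.61, although their near-identical copies make single members uncertain. Class III peroxidases had 14 of 43 higher and 2 lower (median 0.68), expansins 4 of 13 higher (0.77), small heat shock proteins 10 of 20 higher (0.78), and glutathione S-transferases 8 of 34 higher (0.37). Lipid-transfer-like genes had 24 of 54 higher and 4 lower (0.72). A run of 6 adjacent lipid-transfer-like genes on chromosome 4, from 11844506 to 11858970, was higher throughout, with AT4G22485 at 250 and 2471 reads and AT4G22505 at 221 and 2543. Sharing of reads between these copies was not examined. The higher expansins include EXPA7 and EXPA18 of the root marker list, so these families overlap with the root hair genes below, and no separate test of them was made.

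Histone and ribosomal protein genes had medians over those of matched lists. Histone genes had a median of 0.45, with 7 of 37 higher and 1 lower, and ribosomal protein genes 0.34, with only 2 of 73 called higher. Those 2 were RPS6, with 18% covered by reads in both libraries, and OLI7, with 6.14% in wild type and 7.81% in the mutant. Uncounted shared reads may therefore affect the ribosomal family. The ribosomal set, formed by product name, also holds AT5G12110, annotated as a translation elongation factor EF1B. SPCH, the transcription factor gene that starts the stomatal lineage, had 3 and 48 reads (15.2-fold, exact 95% interval 4.90 to 76.3). ERF and DREB transcription factor genes had 18 of 45 lower and 3 higher, with a median of -0.43, and xyloglucan endotransglucosylase genes 6 of 19 lower and 4 higher (-0.21). The medians of WRKY (0.00), VQ-motif (-0.11), calmodulin-like (0.07), UDP-glucosyltransferase (0.08) and DEAD-box genes (0.19) lay inside the range of matched lists. Even so, 8 of 44 WRKY genes were lower and 3 higher, and 7 of 32 calmodulin-like genes were lower and none higher. The VQ-motif family had 2 of 17 lower and none higher, UDP-glucosyltransferases 5 of 80 higher and 2 lower, and DEAD-box genes 1 of 11 each way.

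Transcripts known to respond within minutes to touch or wounding were lower in the crwn1 crwn2 library. A further list of such genes was written after lower stress genes had been seen, so it is not independent of that pattern. In it, 17 of 24 genes were lower, with a median log2 ratio of -1.48, under all 10000 matched lists. PUB23 had 1000 and 185 reads and CML37 103 and 18. This is consistent with wild-type seedlings having responded more to handling before freezing, but a genotype effect on the same genes cannot be separated from it with 1 harvest each. A weaker sustained jasmonate response is left open: only 3 late jasmonate genes were measured, with a median of 1.37. The bootstrap 95% interval over genes, -0.93 to 1.87, only spans the values of those 3 genes. The prediction took a median of 0 or more as evidence against a weaker response. The labelling rule further asked the interval to clear 0, which it does not.

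Root hair genes were higher, which may reflect more root in the mutant sample or more hair-cell expression. In genes not seen before, 5 root hair genes exceeded 11 other root genes by 1.12 in median log2 ratio (-0.68 to 2.18), which alone leaves a larger share of root open. The script also asked for a median above 0.5 in the other root genes before it would favour a larger root share, a bound absent from the prediction. Over all 11 measured root hair genes the difference from those other root genes was 1.93 (1.08 to 2.498), and from all 18 other root genes of both lists it was 1.97 (1.02 to 2.54). In both, 6 of the hair genes are those whose values drew attention to the pattern, so the size of the difference is uncertain. The 18 other root genes had a median of 0.30, and the abundant root gene PYK10 had 8598 and 10188 reads. Of the 11 other root genes not seen before, 10 were above 0. A larger root share would raise genes also expressed in shoots less than genes of roots alone, and shoots were not measured apart. These comparisons therefore do not settle how far a larger root share accounts for the pattern. A shift in root zone or in hair growth stays open and untested.

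AT3G01345 had the largest log2 ratio of the named genes, and whether it is a silenced locus was not examined. A general release of transposable elements could raise such a locus. The share of reads on transposable element genes was 0.970 times that of wild type (0.938 to 1.002), under the 1.5-fold bound set beforehand. The share is a sum that strongly expressed elements can dominate, so a release of weakly expressed ones could leave it almost unchanged. Of 316 listed loci 81 were measured, and 3 of these were higher and 3 lower. Those counts argue against a general release only among the measured element genes. Reads from near-identical copies may not be counted, so a release of such copies cannot be judged. A local difference at that locus, by genotype or by background, was not tested.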
